A study of Homo sapiens with 12 samples.

How the data were processed

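The samples were 12 RNA libraries from human cell lines, 3 each of K562 control, K562 EVI1 overexpression, control labelled MOLM14 and EVI1 overexpression labelled MOLM14, prepared from total RNA with a TruSeq kit per the labels. Groups and replicate numbers were taken from the sample titles. The labels give no batch, date, strand use or poly(A) step, and their extraction text speaks of mouse small intestine although organism and source are given as human cell lines. The deposited values are FPKM (fragments per kilobase and per 1000000 fragments) per gene, made by the authors with STAR, Cufflinks and Cuffnorm on builds given as hg38 and GRCh38, with no tool version stated. Cuffnorm scales libraries against each other, and nothing in the labels speaks of a further correction.

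The table held 58191 rows. Of these, 27 gene symbols had been turned into dates by a spreadsheet and were restored from the Ensembl identifier. A blank row in 3 columns was left out. For 55570 identifiers the exact version was found in GENCODE 29, and coordinates are given for those alone. The row order was checked by comparing control means of both labels in windows of rows, which led to the use of gene names for the libraries labelled MOLM14 in the first 5510 rows only; no row beyond was realigned or renamed. The identifier lists behind both labels evidently differed, so the columns of each label appear to come from separate Cuffnorm runs. For this reason the planned test of labelled MOLM14 control against K562 control was left out by choice, and levels were set side by side without a test.

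Expression was analysed as log2(FPKM + 1), with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 for tables and R 4.3.3 with limma 3.58.1 for tests. Genes with FPKM of at least 1 in at least 3 libraries of a fit were kept. The limma moderated test with a mean-variance trend was fitted separately to the 6 libraries of each label, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes of the fit. A gene is said to be called, to rise or to fall when its adjusted p was under 0.05. The difference of EVI1 effects was tested with limma over all 12 libraries, on rows with usable names that passed the filter under both labels. Overlap of calls was tested with Fisher's exact test per pair of directions, two-sided and adjusted over the 4 pairs. Gene lists, 37 with 973 members fixed from memory of the field before the data were examined, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists with at least 5 tested members, and again with the correlation estimated from the data. Of the members 972 were matched to a row and 348 lay in rows with usable names for both labels. Some genes are members of several lists.

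Named genes follow a rule fixed in advance: MECOM, BCL2, BCL2L1, MCL1, BAX, BAK1, AKT1 and AKT2, with others that are not reported here; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, a separation that chance gives to 10% of genes with 3 libraries against 3; up to 3 called members per list; and, between labels, the 8 largest differences each way and the 8 genes with the strongest shared rise and the 8 with the strongest shared fall. Genes with clone names were passed over. Genes named outside this rule are marked as chosen after their values were seen.

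The depth of the K562 libraries was estimated from the spacing of low FPKM values of genes with 1 transcript, with 89% to 94% of those values within 0.05 log2 of a whole number of reads. No such estimate was made for the libraries labelled MOLM14. FPKM values alone give no count per gene, so no counting interval is given, and overlapping genes on opposite strands as well as near-identical gene copies cannot be told apart. Values of exactly 0 beside replicates of at least 10 FPKM occurred 19 times, 9 of them in mitochondrially encoded genes.

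The pipeline was tested on simulated data, in which independent normal noise was drawn around the control means. The variance of each gene was averaged with the square of the median spread, so genes with a large spread varied less than in the data. Known changes of single genes were added only above a minimum mean expression. With 3 libraries per group, 100 of 100 genes changed by 1 log2 unit were recovered in K562, 97 in the libraries labelled MOLM14 and 98 for the difference of effects. For changes of 0.5 log2 units, 56, 70 and 66 of 100 were recovered. Of all calls, 8.52%, 5.43% and 5% were false. Besides 1 list, 200 genes were changed per simulation, far fewer than were called in the real data. The shares recovered and false depend on that number and need not hold for the real comparisons. A G1/S list shifted by 0.3 log2 units in the K562 simulation gave an adjusted p of 1.1e-32 with the preset and 0.00419 with the estimated correlation; genes in the simulation vary independently, unlike those of real samples.

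Alternatives tried were other pseudocounts, other expression filters, TMM and quantile scaling, rescaling to a common sum, fits without trend, with robust settings, with array weights, with the replicate number as a block or over all 12 libraries, a 2-fold minimum, and each library left out in turn. A test on recovered read counts was not run, since reads can be recovered for genes with 1 transcript alone.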

Results

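RNA sequencing measured gene expression in 12 libraries from human leukaemia cells, 3 in each of 4 groups: K562 control, K562 with EVI1 overexpression, control cells labelled MOLM14, and EVI1 cells labelled MOLM14. EVI1 is a zinc finger transcription factor encoded by MECOM. K562 is a line from chronic myeloid leukaemia in blast crisis that carries BCR-ABL1 and shows erythroid and megakaryocytic features, and MOLM14 is an acute monocytic leukaemia line that carries a KMT2A fusion and FLT3-ITD. The series title names venetoclax, which inhibits BCL2, and capivasertib, which inhibits AKT, but no library carries a drug label. The comparisons here ask which genes differ with EVI1 overexpression under each cell line label, and whether that effect differs between the labels. The deposited FPKM values summed to between 765285 and 898547 per library in K562, and to between 599102 and 630579 in the libraries labelled MOLM14. Low FPKM values of single-transcript genes fell on steps in the K562 libraries, from which depths of 37.4, 67.4 and 58.7 times 1000000 fragments were estimated for the control libraries and of 77.4, 58.7 and 72.3 times 1000000 for the EVI1 libraries. The depth of the libraries labelled MOLM14 is unknown. The labels name no separate cultures, so every p-value measures spread between these samples alone.

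Gene names could be used for the libraries labelled MOLM14 in only the first 5510 of the 58191 rows of the table. In those rows the control means of both labels followed each other row by row, with a Pearson r across genes of at least 0.902 in each of 275 windows of 20 rows and a median of 0.983. From row 5511, the first of 44 identifiers for copies of genes on the pseudoautosomal part of chromosome Y, the columns labelled MOLM14 no longer matched the gene identifiers. In the next window of 500 rows r was 0.051, and it was 0.983 after an offset of 2 rows. Control and EVI1 columns of the same label stayed in step with each other in all 109 windows of 500 rows. Counts of rows for the labelled MOLM14 comparison therefore use every row, and all gene names and gene lists for it use the first 5510 rows alone.

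**Figure D1:**
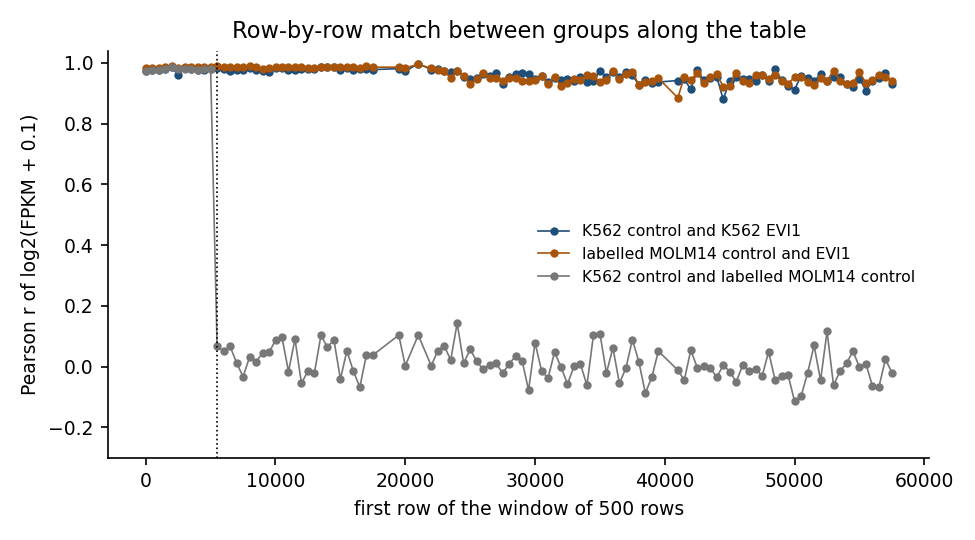
Pearson r of log2(FPKM + 0.1) across genes (vertical axis) between pairs of group means in windows of 500 rows along the deposited table (horizontal axis). The match between K562 control and labelled MOLM14 control ends at the dotted line at row 5511, while control and EVI1 of each label stay matched.

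MECOM itself was higher with EVI1 overexpression under both labels. In K562 it stood at 12.2 ± 2.08 FPKM in control and 24.0 ± 1.94 FPKM in EVI1 libraries (mean ± SD, n = 3 each), a log2 fold change of 0.93 (SE 0.12, adjusted p = 3.4e-04), with 3 of 3 EVI1 libraries above every control. In the libraries labelled MOLM14 it stood at 9.08 ± 0.562 and 17.6 ± 0.617 FPKM, a log2 fold change of 0.88 (SE 0.07, adjusted p = 6.5e-05), again with no overlap. The row is ENSG00000085276.17, on chromosome 3 from 169083499 to 169663618 in GRCh38. The row counts reads over the whole gene, so native and introduced transcripts are not separated. Fold changes throughout are differences of mean log2(FPKM + 1), a scale that understates changes of genes with low FPKM.

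**Figure D2:**
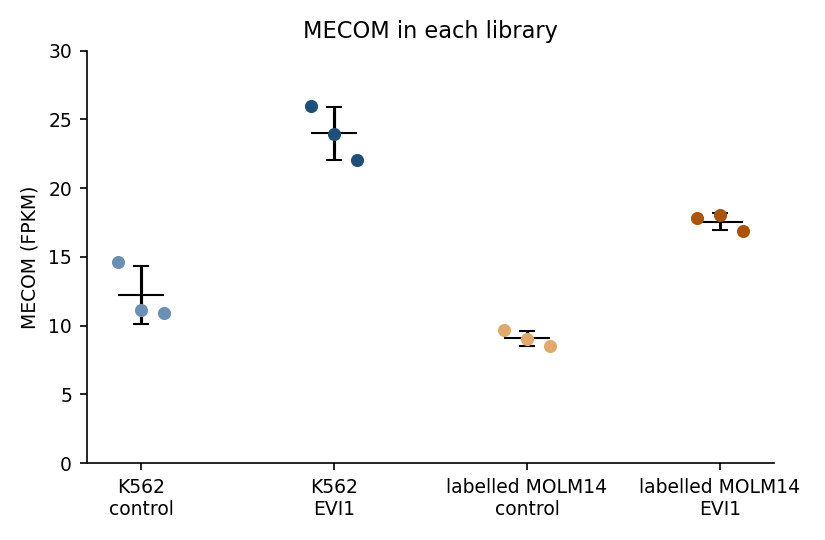
MECOM expression in FPKM (vertical axis) in the 4 groups; each point is a library, the long bar is the mean and the error bar is the SD of 3 libraries. Every EVI1 library lies above every control of its label, with means of 24.0 against 12.2 FPKM in K562 and of 17.6 against 9.08 FPKM in the libraries labelled MOLM14.

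K562 libraries with EVI1 held high levels of several genes that were nearly absent in control libraries, and nearly lacked others. MYEF2 went from 0.217 ± 0.0688 to 40.4 ± 3.56 FPKM (log2 fold change 5.09, SE 0.10, adjusted p = 2.5e-08), and PAEP, which encodes the secreted lipocalin glycodelin, went from 0.434 ± 0.0691 to 43.4 ± 0.695 FPKM. IL15, a growth cytokine for T and NK cells, rose from 0.2999 ± 0.0625 to 31.0 ± 3.54 FPKM, and ULBP2, a stress ligand of the NK receptor NKG2D, from 0.409 ± 0.0422 to 27.5 ± 4.09 FPKM. S100A6, a calcium-binding protein on chromosome 1 from 153534599 to 153536244, fell from 65.7 ± 5.71 to 0.134 ± 0.0548 FPKM (log2 fold change -5.88, SE 0.10, adjusted p = 1.2e-08). DLK1, an imprinted relative of Notch ligands, fell from 35.5 ± 3.22 to 0.131 ± 0.0450 FPKM, and the imprinted noncoding RNA H19 from 45.0 ± 4.94 to 3.39 ± 0.278 FPKM.

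The rest of the 10 largest rises were MT4, BANCR, DTNA, C9orf135, CHAC1 and the carbonic anhydrase CA2, with log2 fold changes from 4.23 for CA2 to 7.84 for MT4. The remaining large falls were in the blood cell lysosomal protein LAPTM5, the neuropeptide precursor GAL, CALN1, AIF1, reelin (RELN), the inflammasome adaptor PYCARD and its relative in innate immune signalling CARD9, from -2.67 for LAPTM5 to -2.10 for CARD9. In all, 7163 of 13800 genes tested passed the threshold, of which 3898 rose and 3265 fell, and 8038 had an unadjusted p under 0.05. At 2-fold or more, 995 rose and 219 fell. Among calls at any fold the excess of rises depends on scaling: rescaling each library to the same sum gave 4106 up and 2169 down, and quantile normalization gave 3347 up and 4105 down. The sums of K562 EVI1 replicate 1 and control replicate 2 lack mitochondrially encoded genes listed at 0 beside high replicates. Rescaling to a common sum raises all other genes of these libraries accordingly. The 2-fold counts were not rerun under other scalings.

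Genes of the amino acid and integrated stress response rose together in K562. Of 25 tested members of the ATF4 list, 20 rose, 0 fell and 5 were not called. CHAC1, which degrades glutathione, went from 1.86 ± 0.425 to 69.7 ± 27.7 FPKM, DDIT4, an inhibitor of mTORC1, from 60.02 ± 15.1 to 995 ± 262 FPKM, and the stress transcription factor ATF3 from 6.10 ± 1.68 to 38.4 ± 8.05 FPKM. The list passed the threshold of camera (adjusted p = 1.2e-06; adjusted p = 0.611 with an estimated correlation). Cholesterol synthesis genes were divided, with 5 of 24 up, 6 down and 13 not called (adjusted p = 0.889, median -0.01, mean 0.09, direction of the test down). CYP51A1, an enzyme of sterol synthesis, had a log2 fold change of -0.78. Of 22 glycolysis genes 6 rose, 4 fell and 12 were not called (adjusted p = 0.990, median -0.04, mean 0.02). Of 77 nuclear genes of oxidative phosphorylation 14 rose, 15 fell and 48 were not called (adjusted p = 0.451). Of 13 mitochondrially encoded genes 0 rose, 3 fell and 10 were not called (adjusted p = 0.0786; 0.0163 without K562 control replicate 2; 0.0304 without the expression filter; 0.0163 to 0.550 over all alternatives), and of the values of 0 in these genes beside high replicates 6 lie in K562 EVI1 replicate 1 and 3 in K562 control replicate 2. Adjusted over the list alone, oxidative phosphorylation counted 12 up and 12 down, and the other lists in this paragraph kept their counts.

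Ribosome biogenesis and DNA replication genes fell in K562. Of 35 members of the MYC and ribosome biogenesis list, 27 fell, 1 rose and 7 were not called (adjusted p = 4.6e-07; adjusted p = 0.550 with an estimated correlation). The nucleolar factors UTP20 and GNL3 had log2 fold changes of -1.24 and -1.01, and the mitochondrial chaperonin HSPE1 one of -0.97. The member that rose was MYC itself, from 173 ± 14.7 to 322 ± 34.97 FPKM (log2 fold change 0.89, SE 0.10, adjusted p = 1.6e-04). In the G1/S list 28 of 40 members fell, 3 rose and 9 were not called (adjusted p = 1.8e-06; adjusted p = 0.550 with an estimated correlation). Cyclin E2 (CCNE2), the maintenance methylation factor UHRF1 and the ribonucleotide reductase subunit RRM2 had log2 fold changes of -1.05, -0.85 and -0.80. Mitotic genes were divided, with 11 of 46 up, 11 down and 24 not called (adjusted p = 0.504). Replication-dependent histone genes rose in 14 of 18 cases, with 1 down and 3 not called (adjusted p = 6.3e-05; adjusted p = 0.550 with an estimated correlation); these near-identical genes share reads, and their transcripts mostly lack a poly(A) tail. Of 72 ribosomal protein genes 3 rose, 16 fell and 53 were not called (adjusted p = 0.0665; 0.0318 under TMM scaling, 0.0227 without K562 control replicate 1, 0.0125 without K562 control replicate 2 and 0.0314 without K562 EVI1 replicate 2; 0.01003 without the expression filter and up to 0.844 over all alternatives). In counts adjusted over the list alone, 3 G1/S genes rose and 30 fell, 15 histone genes rose and 1 fell, 1 ribosomal protein gene rose and 12 fell, and the ribosome biogenesis and mitotic counts were the same.

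Genes of the apoptosis and AKT pathways that the series title points to moved in both directions in K562. Of the BCL2 family members that protect cells, BCL2 lay below the expression filter at 0.316 ± 0.0806 FPKM in control and 0.127 ± 0.0467 FPKM in EVI1 libraries. BCL2L1 (97.7 ± 3.99 and 95.1 ± 8.20 FPKM, log2 fold change -0.04, adjusted p = 0.696) and MCL1 (99.7 ± 2.61 and 110.2 ± 4.68 FPKM, 0.14, adjusted p = 0.1002) did not pass the threshold. BCL2L2 rose from 14.9 ± 0.386 to 23.7 ± 2.26 FPKM and was the 1 member called of 3 tested. Among 11 tested pro-apoptotic members 4 rose, 2 fell and 5 were not called (adjusted p = 0.459). The BH3-only genes PMAIP1, BBC3 and BMF had log2 fold changes of 1.48, 1.24 and 1.18, while the pore-forming BAX (-0.11, adjusted p = 0.494) and BAK1 (0.13, adjusted p = 0.235) were not called. AKT1 rose from 80.6 ± 7.90 to 113 ± 18.2 FPKM (log2 fold change 0.48, SE 0.12, adjusted p = 0.0101), a call lost without the expression filter (adjusted p = 0.0553, against 0.00213 at the lowest over all alternatives). AKT2 was not called (-0.17, adjusted p = 0.180). Of 31 tested components of the PI3K, AKT and mTOR pathway 11 rose, 9 fell and 11 were not called (adjusted p = 0.855, mean 0.01, direction of the test down). The phosphatase gene INPP5D fell (log2 fold change -1.03), and the phosphatase genes INPP4B and PHLPP1 rose (0.90 and 0.67). Of 14 FOXO targets 8 rose, 3 fell and 3 were not called (adjusted p = 0.142; 0.0456 without the expression filter and up to 0.611 over all alternatives). Adjusted over the list alone, the pro-apoptotic list counted 4 up and 3 down and the FOXO list 9 up and 3 down, with the other counts the same.

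Signalling genes rose in several lists in K562. These lists share members, so their results are not separate. Camera at the preset correlation also put 2 to 13 lists past the threshold in the other splits of the K562 libraries, which called at most 1 gene. CDKN1A is in the STAT5, TGF-beta and p53 lists, EGR1 in the ERK and immediate early lists, and MYC in the ERK, STAT5 and ribosome biogenesis lists. In the ERK output list 9 of 15 rose, 1 fell and 5 were not called (adjusted p = 0.0150; 0.0558 without K562 control replicate 3; adjusted p = 0.611 with an estimated correlation), with the early growth response factor EGR1 at a log2 fold change of 2.14 and the AP-1 member FOSL1 at -1.37. In the STAT5 list 10 of 14 rose, 2 fell and 2 were not called (adjusted p = 0.0150; adjusted p = 0.614 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 1.35 and the cytokine feedback gene SOCS3 at 1.08. Among TGF-beta target genes 12 of 20 rose, 4 fell and 4 were not called (adjusted p = 0.0228; 0.0587 without K562 control replicate 3; 0.05004 without K562 EVI1 replicate 1; adjusted p = 0.614 with an estimated correlation), with the pathway inhibitor SMAD7 at 2.23 and BHLHE40 at 1.66. Of 23 p53 targets 12 rose, 3 fell and 8 were not called (adjusted p = 0.0712; 0.0315, 0.0313 and 0.0335 without K562 EVI1 replicates 1, 2 and 3 in turn; 0.0313 to 0.550 over all alternatives). K562 is known to lack functional p53, so this list does not measure p53 activity in K562. Of 21 immediate early and heat shock genes 10 rose, 4 fell and 7 were not called (adjusted p = 0.169), and of 17 NF-kB targets 6 rose, 4 fell and 7 were not called (adjusted p = 0.945). The NF-kB targets, adjusted over the list alone, counted 7 up and 4 down, and the other counts were the same.

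More interferon and antigen presentation genes rose than fell in K562. Among interferon-stimulated genes 12 of 19 rose, 2 fell and 5 were not called (adjusted p = 0.00478; adjusted p = 0.550 with an estimated correlation); IFI27 went from 1.51 ± 0.225 to 12.7 ± 1.66 FPKM. In the antigen presentation list 7 of 9 rose, 0 fell and 2 were not called (adjusted p = 0.00478; 0.0582 without K562 EVI1 replicate 2; adjusted p = 0.550 with an estimated correlation), among them the immunoproteasome subunit PSMB9 at a log2 fold change of 1.74 and the class I gene HLA-C at 1.55, whose reads are uncertain between HLA genes. Of 22 T and NK cell markers only 6 passed the expression filter, TRAC and ZAP70 through the EVI1 libraries alone, and these 6 rose (adjusted p = 2.6e-04; adjusted p = 0.550 with an estimated correlation), including the receptor constant genes TRAC (0.587 ± 0.298 to 8.66 ± 1.08 FPKM) and TRBC2 (5.81 ± 0.553 to 33.4 ± 1.35 FPKM). Members below the filter were not tested and included NKG7, at 0.725 FPKM in control and 0.288 FPKM in EVI1 libraries. The counts of these 3 lists were the same when adjusted over the list alone. Of 38 interferon genes 16 reached a mean of 1 FPKM in control and 20 in EVI1 libraries, and of 22 antigen presentation genes 6 and 10. The tested members of both lists thus include some with a control mean below 1 FPKM.

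Lineage markers in K562 changed in both directions. Of 34 erythroid genes 12 rose, 9 fell and 13 were not called (adjusted p = 0.734), with the haem synthesis enzyme FECH at a log2 fold change of 1.10 and the carbonic anhydrase CA1 at 1.80. Of 15 megakaryocyte genes 8 rose, 1 fell and 6 were not called (adjusted p = 0.0178; 0.0694 without K562 control replicate 3, and 0.155, 0.0987 and 0.216 without K562 EVI1 replicates 1, 2 and 3 in turn; adjusted p = 0.614 with an estimated correlation). The granule transport gene RAB27B had a log2 fold change of 3.33 and the platelet integrin ITGA2B one of 1.48. Of all 27 megakaryocyte list members 11 reached a mean of 1 FPKM in control and 15 in EVI1 libraries. Of 9 monocyte and macrophage genes 4 rose, 4 fell and 1 was not called (adjusted p = 0.775, median 0.04, mean -0.22), with the matrix proteoglycan VCAN at 2.03 and AIF1 at -2.51. Stem and progenitor genes counted 4 up, 3 down and 4 not called of 11 (adjusted p = 0.734), and granulocyte genes 2 up, 0 down and 2 not called of 4. Of 10 tested member genes of the LSC17 stemness score 7 rose and 3 fell (adjusted p = 0.169; 0.0478 without the expression filter and up to 0.697 over all alternatives), with CPXM1 at 3.48. The score itself was not computed, so counts of its genes give no direction of stemness. In the HOXA and MEIS1 list 4 members were tested, of which 3 rose and 1, BMI1, fell. Among the rises, CDK6 (adjusted p = 0.0294) was not called without K562 control replicates 2 and 3 (adjusted p = 0.0769 and 0.0719) and EVI1 replicates 1 and 2 (0.0641 and 0.0756) in turn, with 0.00734 to 0.103 over all alternatives. Integrin and adhesion genes counted 10 up, 4 down and 3 not called of 17 (adjusted p = 0.251), with the hyaluronan receptor CD44 at 2.13 and PECAM1 at -1.63. Drug transporters counted 4 up, 0 down and 2 not called of 6 (adjusted p = 0.0786; 0.0468 without K562 EVI1 replicate 1; 0.0147 without the expression filter and up to 0.550 over all alternatives). Of these, ABCC4 was not called without K562 control replicates 1 and 2 (adjusted p = 0.104 and 0.0857) and EVI1 replicates 1 and 2 (0.108 and 0.0598) in turn, with 0.0102 to 0.108 over all alternatives. Reported EVI1-induced genes counted 4 up, 0 down and 5 not called of 9 (adjusted p = 0.149), with FOS at 1.91, and the 3 tested genes reported as repressed by EVI1 counted 2 up, RUNX1 at 1.25 and MS4A3 at 0.72. Markers of other tissues counted 4 up, 1 down and 1 not called of 6 for intestinal epithelium (adjusted p = 0.166), 2 up of 3 for stroma and endothelium, with COL1A1 at 3.03, and 1 down of 2 for B cells. That call, CD22 (log2 fold change -0.42, adjusted p = 0.0360), was lost without K562 control replicates 2 and 3 (adjusted p = 0.0920 and 0.105) and EVI1 replicates 1, 2 and 3 (0.115, 0.0532 and 0.0760) in turn, with 0.00579 to 0.121 over all alternatives. Adjusted over the list alone, the counts up and down were 12 and 10 for erythroid, 10 and 1 for megakaryocyte, 3 and 0 for EVI1-induced, 5 and 1 for intestinal, and 3 and 0 for stromal genes, and the same for the others.

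The large falls with EVI1 in the libraries labelled MOLM14 included the amino acid response genes ASNS and CTH. Asparagine synthetase (ASNS, chromosome 7 from 97852118 to 97872542) fell from 360 ± 19.0 to 60.5 ± 2.09 FPKM (log2 fold change -2.55, SE 0.06, adjusted p = 6.2e-07), and CTH, which makes cysteine, from 72.7 ± 2.39 to 10.8 ± 1.22 FPKM. The mesenchymal transcription factor TWIST1 fell from 10.7 ± 1.69 to 0.229 ± 0.0578 FPKM (log2 fold change -3.24, SE 0.13, adjusted p = 3.5e-06). SCIN, which encodes the actin-severing protein scinderin (chromosome 7 from 12570577 to 12660179), rose from 0.304 ± 0.0876 to 18.9 ± 1.21 FPKM (log2 fold change 3.93, SE 0.10, adjusted p = 7.9e-07), and the matrix protein SPARC from 2.71 ± 0.981 to 46.6 ± 1.29 FPKM.

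MT4 was listed at 0 in all 3 labelled MOLM14 controls and at 18.4, 12.4 and 23.6 FPKM in the EVI1 libraries. The other large rises among named genes were in MAGEC2, CD3EAP, the neurofilament gene NEFH, DHRS2, MS4A6A, the integrin ITGA4 and NEBL, with log2 fold changes from 1.82 to 3.00. The other large falls were in STAP1, the NKG2D ligand ULBP1, ADGRD1, AKNA, the ATF4 target TRIB3, the serine synthesis enzyme PHGDH and the mitochondrial enzyme PCK2, from -2.50 to -2.12. Over all rows, 7212 of 13315 passed the threshold, 3644 up and 3568 down, and 7976 had an unadjusted p under 0.05. At 2-fold or more, 323 rose and 543 fell. Among the rows whose gene names could be used, 2158 of 3768 passed, 1146 up and 1012 down.

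The amino acid response, ribosome biogenesis and replication lists all passed the camera threshold in the libraries labelled MOLM14. Of 9 tested ATF4 list members 8 fell, 1 rose and 0 were not called (adjusted p = 2.0e-05; adjusted p = 0.156 with an estimated correlation). Of 17 ribosome biogenesis genes 16 rose, 0 fell and 1 was not called (adjusted p = 2.3e-07; adjusted p = 0.0832 with an estimated correlation), with the nucleolar factors NOP16, GRWD1 and RRP9 at log2 fold changes of 1.53, 1.52 and 1.35. Of 21 G1/S genes 16 rose, 1 fell and 4 were not called (adjusted p = 3.0e-04; adjusted p = 0.111 with an estimated correlation), with cyclin E1 (CCNE1) at 0.86 and the helicase subunit MCM4 at 0.74. Of 10 cholesterol synthesis genes 8 fell, 2 rose and 0 were not called (adjusted p = 0.00486; adjusted p = 0.193 with an estimated correlation), with the sterol enzyme MSMO1 at -1.32 and FDFT1, which makes squalene, at -0.97. Heat shock and immediate early genes counted 6 up, 1 down and 2 not called of 9 (adjusted p = 0.0278; adjusted p = 0.193 with an estimated correlation), with the chaperones HSPH1 at 1.65 and HSPA8 at 1.38. Mitotic genes counted 7 up, 4 down and 7 not called of 18 (adjusted p = 0.654), ribosomal protein genes 1 up, 3 down and 17 not called of 21 (adjusted p = 0.734), glycolysis genes 4 up, 5 down and 3 not called of 12 (adjusted p = 0.564), and nuclear oxidative phosphorylation genes 6 up, 1 down and 12 not called of 19 (adjusted p = 0.155). Of the ribosomal protein genes RPL22 and RPLP0 lost their calls with single libraries left out, at adjusted p of 0.0508 to 0.151. Ribosomal protein genes, adjusted over the list alone, counted 0 up and 0 down, and the other lists in this paragraph kept their counts.

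Apoptosis and signalling genes also changed in the libraries labelled MOLM14. BAX rose from 56.6 ± 5.58 to 83.1 ± 8.93 FPKM (log2 fold change 0.55, SE 0.10, adjusted p = 0.00246) and BAK1 from 12.8 ± 0.657 to 18.4 ± 2.02 FPKM (0.48, SE 0.09, adjusted p = 0.00285). BBC3, a BH3-only activator of apoptosis, fell from 19.1 ± 1.79 to 4.79 ± 0.426 FPKM (-1.80, SE 0.09, adjusted p = 9.6e-06). Of 7 pro-apoptotic members 3 rose, 2 fell and 2 were not called (adjusted p = 0.987, median 0.24, mean -0.21, direction of the test down). AKT2 was not called (57.6 ± 5.78 and 61.2 ± 1.15 FPKM, log2 fold change 0.09, adjusted p = 0.347). BCL2, BCL2L1, MCL1 and AKT1 lie in rows that cannot be named. Of 15 components of the PI3K, AKT and mTOR pathway 3 rose, 3 fell and 9 were not called (adjusted p = 0.987, median 0.04, mean -0.03, direction of the test up). FOXO targets counted 1 up, 5 down and 2 not called of 8 (adjusted p = 0.0168; adjusted p = 0.235 with an estimated correlation), with the transcriptional repressor BCL6 at -2.08. The p53 targets counted 1 up, 5 down and 2 not called of 8 (adjusted p = 0.0209; adjusted p = 0.193 with an estimated correlation; 0.0871 without the expression filter), with the death receptor gene TNFRSF10B at -1.45 and BAX the member that rose. STAT5 targets counted 1 up, 4 down and 1 not called of 6 (adjusted p = 0.0282; adjusted p = 0.310 with an estimated correlation), with SOCS2 at -1.22. NF-kB targets counted 2 up, 4 down and 6 not called of 12 (adjusted p = 0.200), TGF-beta targets 2 up, 1 down (SMURF2, not called without MOLM14 control replicates 2 and 3 and EVI1 replicates 2 and 3 in turn, with adjusted p of 0.00515 to 0.0642 over all alternatives) and 4 not called of 7 (adjusted p = 0.619), ERK output genes 2 up and 1 down of 3, and interferon-stimulated genes 1 up and 3 down of 4. Adjusted over the list alone, the counts up and down were 1 and 7 for FOXO, 1 and 6 for p53 and 1 and 5 for STAT5 targets, and the same for the others.

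Adhesion and lineage genes in the libraries labelled MOLM14 included rises of ITGA4 and of the P-selectin ligand SELPLG (log2 fold changes 1.93 and 1.08). Integrin and adhesion genes counted 4 up, 0 down and 3 not called of 7 (adjusted p = 0.0328; 0.121, 0.0995 and 0.0877 without MOLM14 EVI1 replicates 1, 2 and 3 in turn; 0.107 without the expression filter; adjusted p = 0.193 with an estimated correlation). Megakaryocyte genes counted 3 up, 0 down and 2 not called of 5 (adjusted p = 0.0295; 0.153 without the expression filter; adjusted p = 0.193 with an estimated correlation), with RAB27B at 1.69 and the platelet tubulin TUBB1 at 0.97. Erythroid genes counted 4 up, 4 down and 2 not called of 10 (adjusted p = 0.987), with the transferrin receptor TFRC and the erythroid factor KLF1 at 0.72 and 0.77 and the membrane protein XK at -0.83. The 3 tested monocyte genes all fell, TYROBP, CD33 and the lysozyme gene LYZ, at -1.88, -1.65 and -1.17. Of 4 drug transporters 3 rose and 1 was not called, with the efflux pump ABCB1 going from 0.684 ± 0.0287 to 4.79 ± 0.434 FPKM. Member genes of the LSC17 score, which was not computed here either, counted 0 up, 3 down and 2 not called of 5 (adjusted p = 0.0929). Of these, LAPTM4B was not called without MOLM14 EVI1 replicate 3 (adjusted p = 0.0587, with 0.00430 to 0.0587 over all alternatives). Fewer than 5 members were tested for granulocyte genes (CSF3R fell, log2 fold change -1.49), HOXA and MEIS1 (MEF2C fell, -0.97), stem and progenitor genes (MYB fell, -0.27), stroma (ACTA2 rose, 0.64, adjusted p = 0.0307, and 0.0812 without MOLM14 control replicate 3; 0.00437 to 0.0986 over all alternatives), intestinal epithelium (EPCAM fell, -0.74) and B cells (0 called of 1). No member of the remaining lists was tested. Adjusted over the list alone, the counts up and down were 6 and 1 for integrins, 0 and 4 for LSC17 and 2 and 0 for stromal genes, and the same for the others.

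Lineage genes chosen after their values were seen included some with similar and some with different levels in the controls of both labels. The erythroid transcription factor GATA1 stood at 113 ± 8.59 FPKM in the labelled MOLM14 controls, and the erythroid membrane gene RHAG at 359 ± 10.1 FPKM. In K562 controls they stood at 149.8 ± 1.35 and 377 ± 5.66 FPKM. The erythroid genes KLF1 and XK differed more, at 34.5 ± 2.35 and 27.3 ± 2.33 FPKM in the labelled MOLM14 controls against 81.0 ± 4.47 and 7.97 ± 0.492 FPKM in K562 controls. HOXA genes and FLT3, known as highly expressed in leukaemia with a KMT2A fusion, were near 0 in all 12 libraries, with HOXA5, HOXA6, HOXA7, HOXA9, HOXA11 and FLT3 no higher than 0.0245 FPKM in any library labelled MOLM14. Of 12 usable members of the HOXA and MEIS1 list, 2 reached a mean of 1 FPKM in each group. The highest, MEF2C, stood at 37.3 and 51.25 FPKM in K562 control and EVI1. In labelled MOLM14 control and EVI1 it stood at 110 and 56.2 FPKM. LYZ stood at 80.9 ± 1.24 FPKM and TYROBP at 24.8 ± 4.45 FPKM in the labelled MOLM14 controls, against 21.8 ± 1.41 and 3.56 ± 0.518 FPKM in K562 controls. The share of expressed genes whose group means were at least 2-fold apart was 3.7% between K562 control and labelled MOLM14 EVI1. It was 8.5% between both K562 groups, 5.9% between both groups labelled MOLM14, and 12.9% between both controls. K562 EVI1 stood furthest from the other label, with 18.5% of genes apart from labelled MOLM14 control and 15.8% from labelled MOLM14 EVI1. Levels under both labels were set side by side without a test, because the tables appear to have been normalised separately.

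**Figure D3:**
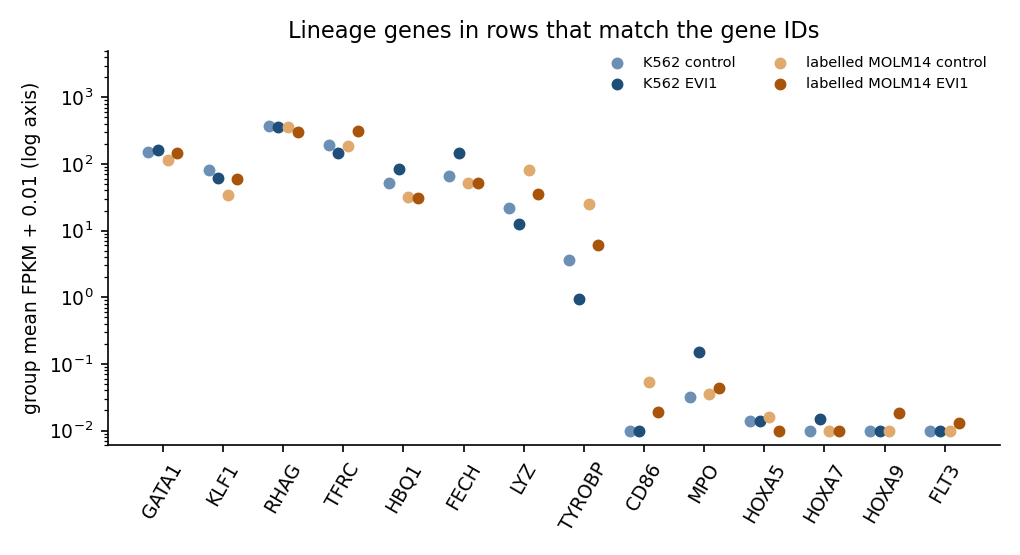
Group mean FPKM + 0.01 (vertical log axis) of lineage genes in rows that match the gene identifiers; each point is the mean of 3 libraries. Erythroid genes from GATA1 to FECH are expressed in all 4 groups, while HOXA genes and FLT3 lie at the floor of the axis in all 4.

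The EVI1 effects of both labels ran against each other across genes. The amino acid response genes ASNS and CTH rose in K562 (log2 fold changes 2.00 and 1.41) and fell in the libraries labelled MOLM14 (-2.55 and -2.64), differences of -4.55 (SE 0.22, adjusted p = 8.8e-10) and -4.06 (SE 0.21, adjusted p = 2.1e-09). The NKG2D ligand ULBP1 and the endoplasmic reticulum stress gene HERPUD1 did the same, with differences of -5.17 and -4.56. The ribosome biogenesis genes UTP20 and RRP15 fell in K562 (-1.24 and -1.38) and rose in the libraries labelled MOLM14 (1.31 and 1.12), differences of 2.55 and 2.50. Median levels of usable ATF4 list members were 36.94 and 59.87 FPKM in K562 control and EVI1. In labelled MOLM14 control and EVI1 they were 89.35 and 35.65 FPKM. In the same order, medians were 88.65, 62.16, 37.01 and 88.78 FPKM for ribosome biogenesis. For G1/S genes they were 41.68, 35.35, 34.54 and 39.5 FPKM. In each of these lists labelled MOLM14 EVI1 lay nearer K562 control than K562 EVI1, without a test. FOXO and p53 medians did not. Of 3697 genes tested under both labels, the effects differed in 2400, 1262 with a higher and 1138 with a lower effect in the libraries labelled MOLM14, and 2509 had an unadjusted p under 0.05.

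Among genes called under both labels, 899 changed in opposite directions and 323 in the same direction. Genes down in K562 and up in the libraries labelled MOLM14 numbered 503, against 312.5 under independence (odds ratio 3.16, 95% interval 2.71 to 3.69, two-sided Fisher's exact test adjusted p = 2.2e-49). Genes up in K562 and down in the other label numbered 396, against 256.9 (odds ratio 2.54, interval 2.16 to 2.98, exact adjusted p = 3.7e-30). Genes up in both numbered 177, against 299.6 (odds ratio 0.408, interval 0.338 to 0.490, exact adjusted p = 1.6e-24), and genes down in both 146, against 267.9 (odds ratio 0.375, interval 0.307 to 0.456, exact adjusted p = 4.7e-26). Across the 3697 genes Pearson's r of the effects was -0.22 and Spearman's rho -0.31. Genes are not independent replicates, so neither these p-values nor r measure evidence from samples.

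**Figure D4:**
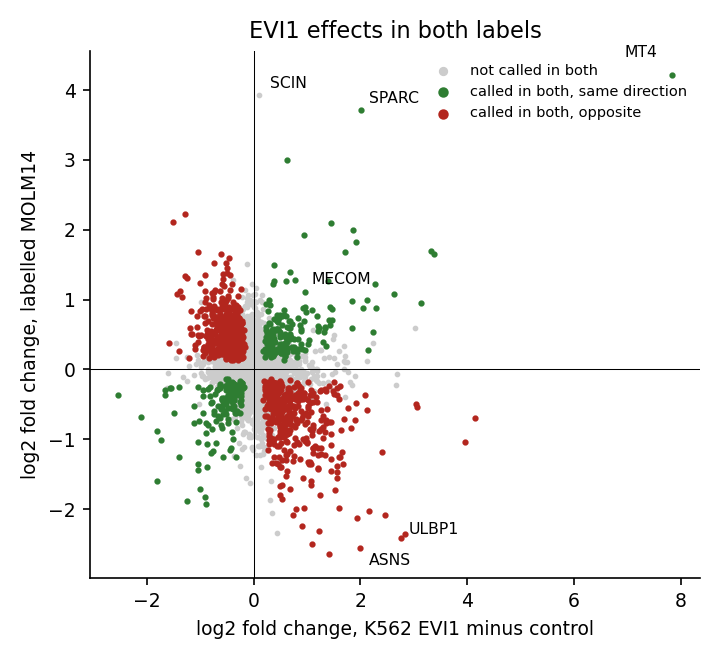
EVI1 minus control log2 fold change in K562 (horizontal axis) against that in the libraries labelled MOLM14 (vertical axis) for 3697 genes tested under both labels; each point is a gene. Genes called under both labels lie mostly in the opposite-direction quadrants, 899 against 323, while MECOM, MT4 and SPARC are higher with EVI1 under both.

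A smaller group of genes changed the same way under both labels. SPARC rose from 68.6 ± 3.81 to 279 ± 16.8 FPKM in K562 beside its rise in the libraries labelled MOLM14. MS4A6A, NEBL, RAB27B, MS4A4A, DHRS2 and CYP26A1, which degrades retinoic acid, rose under both labels, with log2 fold changes of at least 1.44 under each. For CYP26A1 they were 1.72 and 1.68, a difference that was not called (-0.04, SE 0.19, adjusted p = 0.863). It was not called for MS4A6A and NEBL either. The size of the shared rise did differ between labels for MT4 (-3.63), SPARC (1.71), RAB27B (-1.64), MS4A4A (-1.72) and DHRS2 (0.65). The blood cell genes WAS, TYROBP and LCP2 fell under both, as did LAMB1, TMEM156, the leptin receptor LEPR, IGF1 and TP63. WAS, which organises actin in blood cells, had log2 fold changes of -1.81 and -1.59. Among the shared falls the difference was called for TYROBP, LCP2, IGF1 and TP63, and not for WAS, LAMB1, TMEM156 and LEPR.

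Gene lists were tested for the difference of effects only after the single-label results had been seen. Of 20 lists with at least 5 tested members, 6 passed the camera threshold and 0 did with an estimated correlation. The effect was higher in the libraries labelled MOLM14 for 17 of 17 ribosome biogenesis genes (adjusted p = 3.9e-08; adjusted p = 0.155 with an estimated correlation) and for 18 of 21 G1/S genes (adjusted p = 6.9e-05; adjusted p = 0.114 with an estimated correlation). It was lower for 8 of 9 ATF4 list genes and higher for 1 (adjusted p = 1.1e-04; adjusted p = 0.378 with an estimated correlation). STAT5, FOXO and p53 targets also passed, with 4 of 6, 5 of 7 and 6 of 8 members lower (adjusted p = 0.0260, 0.0276 and 0.0347; adjusted p = 0.391, 0.198 and 0.378 with an estimated correlation).

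**Figure D5:**
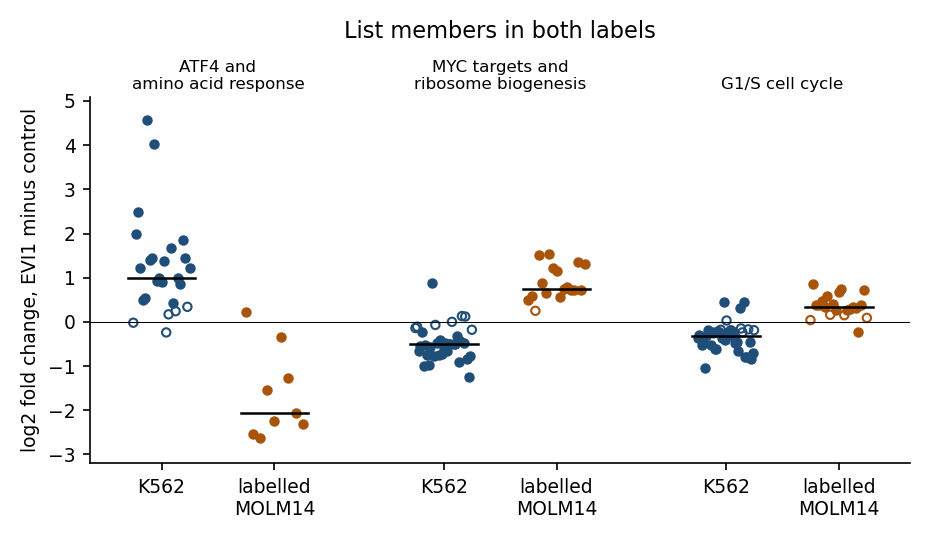
EVI1 minus control log2 fold change (vertical axis) of each tested member of 3 gene lists in K562 and in the libraries labelled MOLM14; filled points passed the test, open points did not, and bars are medians. Of the ATF4 list 20 of 25 rose in K562 and 8 of 9 fell in the libraries labelled MOLM14, and the ribosome biogenesis list shows the reverse, with 27 of 35 down and 16 of 17 up.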

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

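The tests of row order, HOXA and FLT3 levels, shares of genes 2-fold apart, quantile scaling, MECOM direction, the correlation outside 3 lists and T-cell genes were chosen after the results they bear on had been seen, while the counts over other splits of the samples were planned.

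The EVI1 effect differed between both labels for 2400 of 3697 genes in limma's test of the difference. The largest positive differences, labelled MOLM14 minus K562 on the log2 scale, were 3.83 for SCIN, 3.63 for NEFH, 3.51 for CD3EAP, 2.72 for KISS1R, 2.63 for PUS7, 2.55 for UTP20, 2.51 for SELPLG and 2.50 for RRP15. The largest negative ones were -5.18 for ADGRD1, -5.17 for ULBP1, -5.00 for GCA, -4.85 for TFPI, -4.56 for HERPUD1, -4.55 for ASNS, -4.19 for NFATC4 and -4.06 for CTH. Of 100 splits of the samples within labels, 1, the real one, gave as many genes with a difference; the highest other count was 1828, from the split that exchanges control and EVI1 under 1 label. Genes called in opposite directions numbered 899 in the real split, the 1 of 100 that gave as many, and 323 in the highest other, again that exchange. Other splits of a label undo the EVI1 effect itself and call at most 1 gene, so neither count of splits tells whether the effects differ or oppose by chance, and the difference rests on limma's test alone.

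For the comparisons within a label the 10 possible splits of 6 libraries are too few for a share under 0.05. The real split was the 1 with the most called genes in K562 (7163, highest other 1) and in the libraries labelled MOLM14 (7212, highest other 1). Gene lists past the camera threshold numbered 10 in the libraries labelled MOLM14, where the real split was the 1 with the most and the highest other gave 5. In K562 they numbered 11, and 3 of 10 splits gave as many, the highest other 13, in a split that puts K562 control replicates 1 and 3 and EVI1 replicate 2 together. Both K562 splits with 12 and 13 lists called 0 genes and set control replicates 1 and 3 apart from control replicate 2. The lowest other count of lists was 2 in K562 and 1 in the libraries labelled MOLM14. Camera at the preset correlation thus passed lists in every split. With an estimated correlation 0 lists passed under either label.

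The libraries labelled MOLM14 resemble K562 control in HOXA and FLT3 levels and in the erythroid genes GATA1 and RHAG. Between the controls of both labels, KLF1 and XK lay over 2-fold apart. Rows out of place are argued against by the match of control means, with a lowest r of 0.902 over windows of 20 rows. K562 cells mixed into MOLM14 cells are argued against by HOXA5, HOXA6, HOXA7, HOXA9, HOXA11 and FLT3. These genes stood at no more than 0.0245 FPKM in any library with that label. The same levels argue against RNA of MOLM14 cells as labelled, since such genes are known as highly expressed with a KMT2A fusion. What stays open is a hypothesis, that the MOLM14 label may stand on RNA derived from K562 or a closely related line: 3.7% of expressed genes were 2-fold apart between K562 control and labelled MOLM14 EVI1, fewer than the 8.5% between both K562 groups. Going the other way are 12.9% between both controls, with LYZ, TYROBP and MEF2C above their K562 levels. MEF2C, from the same list as the HOXA genes, stood at 110 FPKM in labelled MOLM14 control against 37.3 FPKM in K562 control. So are 18.5% and 15.8% between K562 EVI1 and the labelled MOLM14 control and EVI1 groups. LYZ, TYROBP and MEF2C were picked after their values were seen. Of 10 monocyte and macrophage genes in usable rows, 3 reached a mean of 1 FPKM in K562 control and 3 in labelled MOLM14 control. Shares across labels compare levels that appear to have been normalised separately. No genotype was analysed here, and reads would be needed to settle the hypothesis.

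The EVI1 effects under both labels ran opposite across genes. A scaling factor common to all genes shifts their log2 effects about equally and hardly changes a correlation across genes. The correlation of effects after quantile normalization within each label, -0.18 against -0.22 before, is therefore a weak test of scaling. Counts of calls do depend on scaling. After quantile normalization 887 genes were called in opposite directions and 371 in the same direction, against 899 and 323 before, so the excess of opposite calls remained. An exchange of control and EVI1 under 1 label is argued against by MECOM, which rose by at least 0.88 under each. A culture state of single arms, such as nutrient supply or density at harvest, cannot be told apart from the EVI1 effect. Each arm may stem from 1 culture. Such a state may lie in the labelled MOLM14 control as well as in an EVI1 arm. In the medians of the ATF4, ribosome biogenesis and G1/S lists, labelled MOLM14 EVI1 lay nearer K562 control than K562 EVI1. Outside these lists the correlation was -0.20 over 3650 genes, which a state that moves further genes leaves open. A difference in how cells under each label respond to EVI1 stays open as well, untested.

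Genes of the T-cell receptor complex rose in K562 with EVI1, TRAC from 0.587 to 8.66 FPKM, TRBC2 from 5.81 to 33.4 FPKM and CD3D from 38.5 to 60.8 FPKM. T cells as the whole source in the EVI1 samples are argued against by CD2, CD5, CD3E, CD3G, LCK and IL7R, whose median was 0.191 FPKM in that group, far below TRAC and TRBC2. Of these, LCK (0.0531 to 0.381 FPKM), CD3E (0.0741 to 0.295 FPKM), CD3G (0.358 to 0.592 FPKM) and IL7R (0.00125 to 0.0864 FPKM) were higher than in control, and CD2 (0.0467 to 0.00301 FPKM) and CD5 (0.0634 to 0.0603 FPKM) were not. CD3D was already at 38.5 FPKM in the controls without EVI1 overexpression. Transcription of these loci in K562 cells stays open as a hypothesis, and reads shared between TRBC2 and its near-identical neighbour TRBC1 were not separated.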

How the results depend on the processing

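Fits to rows with usable names alone, fits without rows that hold a lone 0, quantile scaling of the overlap and all settings of the correlation of effects were chosen after seeing the data; the other alternatives were planned. MECOM kept its direction and its call under every alternative run, from 0.79 with array weights to 1.05 in K562 and from 0.84 to 0.95 in the libraries labelled MOLM14. Called genes in K562 fell from 7163 to 2241 when rows with usable names were fitted alone and to 1214 with a 2-fold minimum, and in the libraries labelled MOLM14 from 7212 to 2233 and 866, since both alternatives admit fewer genes. The 2-fold minimum left 689 genes with a difference of effect and 49 called in opposite directions, with 19 called in the same direction. Leaving out each library in turn gave 5591 to 6818 calls in K562, 5975 to 6386 in the libraries labelled MOLM14, 2275 to 2405 for the difference, 715 to 913 opposite calls and r of the effects from -0.29 to -0.20; r was -0.16 with a pseudocount of 0.1 and without the expression filter. Lists past the threshold numbered 8 to 13 in K562 and 9 to 10 in the libraries labelled MOLM14 with a library left out, 17 in K562 and 7 in the libraries labelled MOLM14 without the expression filter (the cause was not tested), and 0 under either label with an estimated correlation. No list changed direction while past the threshold under any alternative run. Ranks in camera gave 11 and 10.

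Among single genes, BCL2L1 in K562 turned to 0.03 when rescaled to a common sum and BAX to 0.00 without K562 control replicate 2, neither of them called; BAX was called without K562 control replicate 3 (-0.28, adjusted p = 0.0166, with 0.0166 to 0.998 over all alternatives). With array weights MCL1 (adjusted p = 0.0252, with 0.0252 to 0.289 over all) and AKT2 in K562 (adjusted p = 0.0161, with 0.0161 to 0.468 over all) were called. In all, 5227 values of single genes under alternatives kept direction and side of the threshold, 66 lost a call, 3 gained one and 2 turned; the cause was not tested. No scaling moved the median of all genes by over 0.1 on the log2 scale.

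The labels do not say what replicate numbers pair, and the values showed no sign of pairing. Between residuals of same-numbered control and EVI1 libraries, r across genes was -0.21, -0.05 and 0.13 in K562. In the libraries labelled MOLM14 it was -0.01, -0.03 and -0.05. Differently numbered libraries gave -0.24 to 0.22 in K562 and -0.01 to 0.04 in the libraries labelled MOLM14. With the replicate number as a block, 7044 and 7098 genes were called under the respective labels, 2449 for the difference and 875 in opposite directions, with 11 and 10 lists. The comparison of both controls and the test on recovered read counts, both planned, were not run, the first because the labels appear normalised separately and the second because FPKM gives reads for genes with 1 transcript alone. Depth is unknown for the libraries labelled MOLM14, which leaves the precision of their low values open.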

Other observations

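Metallothionein genes on chromosome 16 were looked up after the level of MT4 had been seen. MT4, a metal-binding protein known from stratified epithelium, was listed at 0, 0.236 and 0 FPKM in the K562 controls and at 215, 247 and 280 FPKM in the K562 EVI1 libraries; the labelled MOLM14 controls were listed at 0 and the EVI1 libraries at 18.4, 12.4 and 23.6 FPKM. Its neighbour MT3 reached at most 0.0467 FPKM in any library. MT2A, a broadly expressed metal-responsive gene, rose in K562 from 17.7 ± 3.11 to 59.2 ± 6.28 FPKM (log2 fold change 1.69, SE 0.13, adjusted p = 1.9e-05). MT1G was not called (adjusted p = 0.0715). MT1X stood at 9.89 ± 0.620 and 12.0 ± 0.870 FPKM (adjusted p = 0.0442), and MT1E, MT1F, MT1H, MT1A and MT1M lay below the expression filter. Reads are uncertain between these similar genes.

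TFPI, an inhibitor of blood coagulation, went from 36.7 ± 1.90 to 665 ± 34.7 FPKM in K562 with EVI1 and from 74.1 ± 11.5 to 44.9 ± 2.58 FPKM in the libraries labelled MOLM14. GCA, which encodes the calcium-binding protein grancalcin, went from 0.119 ± 0.0779 to 16.4 ± 1.29 FPKM in K562 and from 5.58 ± 0.390 to 2.21 ± 0.411 FPKM in the libraries labelled MOLM14.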
